A study of Rattus norvegicus with 6 samples.

How the data were processed

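Circular RNA was measured in white matter of 6 rats, 3 from a cerebral palsy model and 3 normal controls, with 1 library per rat. Circular RNAs (circRNAs) are closed loops formed when a downstream splice donor joins an upstream acceptor, and they are counted by reads that cross this back-splice junction. Per the labels' protocols, total RNA was treated with RNase R, an exonuclease that digests linear RNA, then fragmented, primed with random hexamers, amplified by PCR and sequenced as 150 bp paired-end reads. How the cerebral palsy model was made, and the age and sex of the rats, are not given in the sources used here. The aligner and the circRNA caller are not given in the sources used here either. The genome build was mRatBN7.2, per the submitters' processing notes, and all coordinates are 1-based positions in that build as the authors' table lists them.

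The authors deposited a table of 11123 circRNAs. For each library it holds raw counts of junction reads, per the file headers. It also holds a normalised signal that the authors named SRPBM, per the file headers. The SRPBM values were tested against the counts, and each equals the count times a constant over 1 divisor per library, from 40063350 to 44429250. Each divisor is an exact multiple of 150, the read length, which plain read counts would hardly all be. The divisors thus appear to be a count times the read length. What was counted is not given, so SRPBM levels are read only as relative values. The deposited log2 fold changes were the log2 ratio of the group means of SRPBM in 1873 of 1873 comparable circRNAs (largest gap 5.33e-15), and were infinite where 1 group had no read. The authors' deposited p-values and q-values came from a test that is not given in the sources used here. The deposited number of exons per circRNA was used only to describe the circRNAs. The table separates exonic circRNAs (9478 entries) from ciRNAs (1645 entries), circular RNAs derived from introns.

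Junction reads per library were 6793, 6285 and 5926 in controls 1 to 3 and 5821, 4750 and 5697 in model rats 1 to 3. Counts this low limit the precision. A count of 0 in 1 library allows up to 3 reads, which is 0.0442% to 0.0632% of that library's junction reads. Libraries were amplified by PCR and the table gives no molecule counts, so such limits cover counting error only. Of the 11123 entries, 2488 had no read in any of the 6 libraries and were left out. Host-gene names were taken from the authors' table. Of 4254 names, 4141 matched a symbol or synonym in a RefSeq table of the GRCr8 assembly, which was used for names only.

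Before the data were examined, groups were assigned from the sample labels and the tests, gene lists and naming rule were fixed. Back-splice counts per circRNA were tested with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood, with TMM scaling, full library totals and the default low-count filter (filterByExpr, min.count 10, min.total.count 15). Benjamini-Hochberg adjustment ran over all circRNAs tested, with a threshold of 0.05 and no fold cut-off. The same test was run on reads summed over all circRNAs of a host gene, which measures the circular output of a gene and not its mRNA. Levels are reads per 1000 TMM-scaled junction reads. The standard error of each log2 fold was derived from the fold and its F statistic. Use of alternative circRNAs within a host gene was tested with limma 3.58.1 (voom and diffSplice).

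A set of 20 gene lists covered cell types of white matter and neighbouring tissue, myelin lipid synthesis, hypoxia, inflammation, cell death, cell cycle, axon guidance, neuronal function, circRNA biogenesis factors and hosts of circRNAs widely described in brain. Lists with at least 5 tested host genes were tested with camera in limma at a preset correlation of 0.01 on log2 CPM computed here from the deposited counts with prior count 2. Only 1 list reached 5 tested members. After the data were seen, camera at a filter of 6 reads over all libraries was therefore added. An edgeR test of the reads summed over all members of each list, scaled by library totals, was added as well. Both were also run without each library in turn and with the replicate number as a block. Also added after the data were seen were the 6-read and 10-read filters for the tests of single features, the authors' divisors as library sizes, DESeq2 without a filter, and the comparison of junction reads per divisor.

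A set of 4 measures of whole libraries were compared by exact two-sided permutation tests, for which 3 against 3 samples give no p below 0.1. They were the number of distinct circRNAs after thinning each library to 4750 reads (mean of 20 seeded draws), the share of reads in the 10 most abundant circRNAs, the ciRNA share, and the mean log2 genomic span of exonic circRNAs. The alternatives chosen before the data were seen were DESeq2 1.42.0, limma voom, other scaling and filters, a replicate block and leaving out each library in turn.

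Named circRNAs were chosen by rule. The rule took those past the threshold whose groups did not overlap, up to 10 in each direction, filled with the smallest unadjusted p of that direction. It also took the 10 most abundant circRNAs, 5 host genes in each direction by the same rule, and the 4 members of each list with the smallest p. Entries listed only by an identifier were skipped, and 1 host gene that the rule takes is not reported here. Any other circRNA or host gene named in the text was chosen after its values were seen. Such items are marked in the text.

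The edgeR step was tested on simulated counts for this comparison, with 200 features changed per simulation and a mean of 78.9 circRNAs passing the filter. Most changed features did not pass this filter and so were not tested. Over 10 simulations pooled, edgeR called 10 of the 35 tested circRNAs changed 2-fold (28.6%), 61 of 72 changed 4-fold (84.7%) and 104 of 104 changed 8-fold. For host-gene sums, with a mean of 123.4 tested, it called 8 of 47 (17%), 82 of 96 (85.4%) and 127 of 127 of the changed hosts that passed the filter. At the filter of 6 reads over all libraries the shares called of changed features tested were 2.75%, 24.2% and 54.6% for circRNAs and 1.6%, 25.5% and 55.9% for hosts. False calls made up 6.91% of all calls for circRNAs and 5.65% for hosts at the first filter. Simulated counts at both levels used the common dispersion of the circRNA fit. With no change simulated, 1 of 20 simulations gave any call. No pair of libraries agreed within sampling noise, as a library deposited again would (chi-square over degrees of freedom from 1.86 to 3.34). Each library, from a separate rat per the labels, counts as 1 replicate.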

Results

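Back-splice junction reads were counted in RNase R-treated RNA from white matter of 3 cerebral palsy model rats and 3 normal control rats. The libraries held 4750 to 6793 junction reads each, 35272 in all. A total of 8635 circRNAs from 3696 host genes had at least 1 read, 7461 of them exonic and 1174 ciRNAs. Most were rare: 4514 (52.3%) rested on a single read, and 561 had at least 10 reads and held 54% of all reads. Junctions on the Y chromosome had 13 reads in controls and 0 in model rats, and the sex of the rats is not given in the labels. Only 238 circRNAs had a read in each of the 6 libraries.

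The most abundant circRNA came from Nfix, a nuclear factor I transcription factor gene (circRNA746, chromosome 19, 23383322 to 23383853, 1 exon). It stood at 27.8 ± 4.61 reads per 1000 in controls and 30.5 ± 8.39 in model rats (SD, n = 3). Over both groups pooled, next was Atrnl1 circRNA2141, described with the changed circRNAs; in model rats it stood below the Unc79 and Dtnb circRNAs. Unc79 circRNA1253, from a gene for a subunit of the sodium leak channel complex, stood at 8.99 ± 1.51 in controls and 9.78 ± 2.08 in model rats. Dtnb circRNA1168, from the dystrobrevin beta gene, stood at 8.52 ± 1.21 and 8.11 ± 2.08, and Zfp532 circRNA848, from a zinc finger gene, at 7.81 ± 1.03 and 7.90 ± 1.52. Arid1a circRNA1417, from a SWI/SNF chromatin remodelling gene, stood at 7.40 ± 2.62 and 7.37 ± 2.81, and Setbp1 circRNA863 at 6.17 ± 2.32 and 6.55 ± 1.90. Ttc3 circRNA189 stood at 5.76 ± 1.27 and 4.62 ± 2.09, Bbs9 circRNA2286 at 4.97 ± 0.405 and 6.27 ± 1.15, and Ralgapa1 circRNA1211 at 3.92 ± 0.691 and 6.20 ± 2.36 (all SD, n = 3, reads per 1000, control first). Apart from the Atrnl1 circRNA, none of these 10 passed the test between groups, and the sign of the fold of Nfix, Unc79, Dtnb, Zfp532, Arid1a, Setbp1 and Ttc3 circRNAs turned under at least 1 alternative setting. Some hosts gave many circRNAs: 37 were detected from Nbea, 29 from Lrp1b (both named after their values were seen) and 25 from Atrnl1. Exonic circRNAs held a median of 4 exons per read and spanned a median of 12086 bp of genome, while ciRNAs spanned a median of 335 bp.

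The design asks which circRNAs differ between model and normal white matter. A circRNA of Erbin, which encodes a scaffold protein that binds the receptor ErbB2, was 3.45-fold lower in model rats. This circRNA (circRNA1769, chromosome 2, 34996216 to 35001254, minus strand, 3 exons) fell from 6.86 ± 2.77 to 1.98 ± 0.561 reads per 1000 (SD, n = 3). Its reads were 36, 63 and 31 in controls and 14, 10 and 8 in model rats. The most abundant circRNA of Atrnl1, which encodes the attractin-like transmembrane protein, was 2.33-fold lower (circRNA2141, chromosome 1, 256809960 to 256860110, plus strand, 5 exons). It fell from 18.7 ± 3.32 to 7.97 ± 3.54 reads per 1000 (SD, n = 3), with 139, 93 and 123 reads in controls against 65, 22 and 45 in model rats. Every model library lay below every control library for both.

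**Figure D1:**
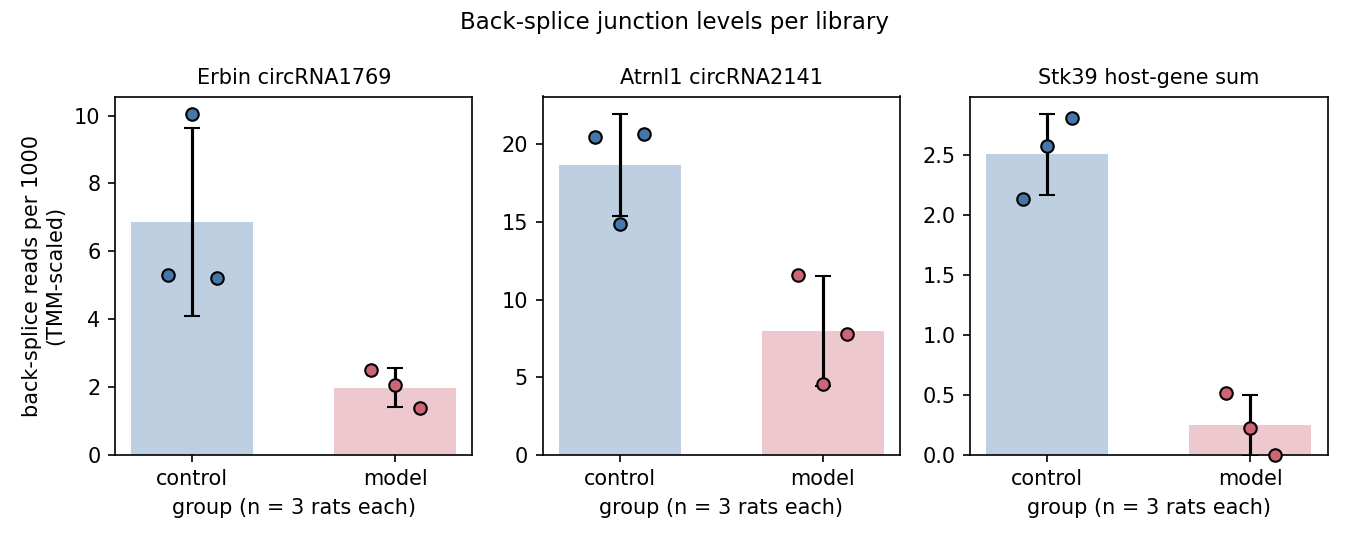
Back-splice reads per 1000 TMM-scaled junction reads (vertical axes, linear) by group for Erbin circRNA1769, Atrnl1 circRNA2141 and the summed circRNAs of Stk39; points are libraries, bars are group means and error bars are SD over 3 rats. The group means are 6.86 against 1.98 for the Erbin circRNA, 18.7 against 7.97 for the Atrnl1 circRNA and 2.51 against 0.244 for Stk39, and the groups do not overlap in any of these.

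In edgeR's quasi-likelihood test of 60 circRNAs, these 2 passed an adjusted p of 0.05 and none was higher in model rats. The log2 fold was -1.79 ± 0.42 (SE) for the Erbin circRNA, with adjusted p = 0.00935 in edgeR. For the Atrnl1 circRNA it was -1.22 ± 0.34 (SE), with adjusted p = 0.0323 in edgeR. Over all 60, 30 log2 folds were negative and 30 positive (median 0.003). Scaling within junction reads tends to centre the folds near 0, so this split cannot show a general fall. With the authors' divisors the median was -0.22. At an unadjusted p under 0.05, where a share of 0.05 falls by chance, there were 4 of the 60 circRNAs, all lower. The other 2 were a single-exon circRNA of Slc8a1, the sodium-calcium exchanger gene (circRNA1138), with log2 fold -1.203 ± 0.47, and Tlcd4 circRNA1876, with -1.01 ± 0.46 (SE, edgeR adjusted p = 0.298 and 0.544). With 1 library left out, the Tlcd4 fold ranged from -1.65 without model rat 3 to -0.56 without model rat 1. Further lower values that did not pass ranged from -0.46 (Fbxl17 circRNA2254) to -0.77 (Yme1l1 circRNA493), and included a 4-exon Eri3 circRNA, Hdac2 circRNA910 and Thoc2 circRNA983. On the higher side, 10 circRNAs ranged from a log2 fold of 0.33 (Eri3 circRNA1394) to 0.85 (Kdm6a circRNA933), none with an edgeR adjusted p below 0.889. The Kdm6a circRNA had 20, 0 and 17 reads in controls against 20, 17 and 20, and its fold was 0.27 without control 2 and 1.26 without control 3. The 10 came from Ralgapa1, Dennd1b, Kdm6a, Rere, Mtmr7, Bbs9, Sergef, Arsb, Arhgap32 and Eri3. Of the 60, 7 had groups that did not overlap (11.7%, against 10% by chance). With any 1 of the 6 libraries left out the Atrnl1 circRNA no longer passed in edgeR (log2 fold -1.52 to -0.89), and the Erbin circRNA (-2.002 to -1.40) passed only without model rat 2 (edgeR adjusted p = 0.0195); these fits had fewer samples and tested 79 to 90 circRNAs. With DESeq2 size factors in edgeR neither passed (adjusted p = 0.0547 for Erbin and 0.146 for Atrnl1), and with no filter none of 8635 circRNAs passed.

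Summing all circRNAs of a host gene asks which genes differ in circular output. Stk39 encodes the kinase SPAK, which regulates cation-chloride cotransporters, and its summed circRNAs were 9.36-fold lower in model rats. They fell from 2.51 ± 0.341 to 0.244 ± 0.256 reads per 1000 (SD, n = 3), with 15, 17 and 16 reads in controls against 3, 1 and 0. Most of these reads came from 1 junction, circRNA1632 (named after its values were seen), with 38 in controls and 3 in model rats. The Erbin sum was 3.32-fold lower, from 6.87 ± 2.47 to 2.06 ± 0.59 reads per 1000 (SD, n = 3). Its reads were 36, 64 and 33 in controls against 15, 10 and 8. Nearly all of them are those of circRNA1769 described above, so this is not a separate result. The Atrnl1 sum over 25 circRNAs stood at 24.5 ± 4.53 in controls and 11.4 ± 4.04 in model rats and narrowly missed the threshold (log2 fold -1.10 ± 0.29, SE, edgeR adjusted p = 0.0543). Of 107 host genes tested with edgeR, Stk39 (log2 fold -3.23 ± 0.76) and Erbin (-1.73 ± 0.42) passed, each at adjusted p = 0.0366, and none was higher. Over all 107, 51 log2 folds were negative and 56 positive (median 0.042), again after scaling within junction reads. With the authors' divisors the median was -0.23. At an unadjusted p under 0.05, where a share of 0.05 falls by chance, there were 3 of the 107 host genes, all lower. Next on the lower side, without passing, were Rasa2 (-1.05 ± 0.51), a Ras GTPase-activating protein gene, and Yme1l1 (-0.74 ± 0.37), a mitochondrial protease gene. On the higher side, without passing, were the neurotrophin receptor genes Ntrk3 (log2 fold 0.98 ± 0.51) and Ntrk2 (0.82 ± 0.47), Slc41a2 (0.87 ± 0.45), the autophagy gene Ambra1 (0.81 ± 0.46) and Arhgap32 (0.63 ± 0.35), with edgeR adjusted p = 0.779 for each. A circRNA of Ntrk2 and one of Ambra1 had no read in control 3 and at least 7 in each other library. Groups did not overlap in 15 hosts, 14% of those tested against 10% by chance. Neither call was kept without any 1 control, model rat 2 or model rat 3, while the log2 fold over left-out libraries ranged from -4.43 to -2.66 for Stk39 and from -1.97 to -1.37 for Erbin. Without model rat 1 both passed (edgeR adjusted p = 0.00464 and 0.00836). DESeq2 without a filter called 0 of 3696 host genes. In limma voom Stk39 did not pass (adjusted p = 0.122) and Atrnl1 did (adjusted p = 0.0212).

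The gene lists ask whether circRNAs of a cell type or pathway moved together. Hosts active in myelinating oligodendrocytes held 1.12% ± 0.341 of junction reads in controls and 0.743% ± 0.506 in model rats (SD, n = 3), with 210 and 115 reads over 25 detected hosts. The log2 fold of their summed reads was -0.61 ± 0.29 (SE), with edgeR adjusted p = 0.799, and it was -0.74 without Ptprd. Among them, Tmeff2 had 12, 9 and 12 reads in controls against 4, 7 and 5, and Edil3 had 4, 2 and 6 against 1, 1 and 0. Phlpp1 had 9, 7 and 6 against 4, 4 and 4, while Ptprd, the most abundant, had 18, 17 and 23 against 3, 27 and 8. Over the 12 members with at least 6 reads the median log2 fold was -0.77. Of these 12, only Pex5l, with 1, 2 and 5 reads against 4, 5 and 4, and Zfp536, with 1, 1 and 7 against 7, 2 and 1, went the other way. The members named here were picked for description after their values were seen, except Ptprd, and none passed. In camera at the 6-read filter the list lay below other hosts at adjusted p = 0.0261 with the preset correlation, but adjusted p = 0.749 with an estimated correlation. With limma's fry test at this filter its adjusted p was 0.347. These 3 values were adjusted over 6 lists, the list sums over 20. Without model rat 2 the list sum passed (log2 fold -1.30 ± 0.33, edgeR adjusted p = 0.0154), and without model rat 3 it was -0.33 ± 0.33 (edgeR adjusted p = 0.9). The astrocyte list stood at 0.514% ± 0.0504 and 0.364% ± 0.083 (SD, n = 3), with 52.9% of its reads from Prex2 (log2 fold -0.55 ± 0.44). Cholesterol and lipid synthesis hosts stood at 0.308% ± 0.0986 and 0.213% ± 0.0538, with Acaca, named after its values were seen, the most abundant (all control first).

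Hosts of the glutamate receptor and postsynaptic density list, among them Grm5 (log2 fold 0.42 ± 0.58) and Magi2 (-0.18 ± 0.71), took 1.21% ± 0.216 of reads in controls and 1.33% ± 0.375 in model rats. Synaptic release hosts, among them Cadps (-0.46 ± 0.50) and Rims1 (-0.35 ± 0.53), took 1.14% ± 0.0664 and 1.08% ± 0.298. Hosts of the voltage-gated ion channel list took 1.35% ± 0.131 and 1.38% ± 0.359 (SD, n = 3). The list is broader than its name: the sodium-calcium exchanger gene Slc8a1 held 23.7% of its reads. The log2 fold was -0.86 ± 0.43 for Slc8a1 and 1.21 ± 0.75 for Cacna2d3, a calcium channel subunit gene. The fold signs of Grm5, Magi2, Ptprd and Rims1 turned when 1 library was left out. Without model rat 1 the Cacna2d3 sum passed (edgeR adjusted p = 0.0257), and over left-out libraries its fold ranged from 0.66 (without model rat 3) to 2.14 (without control 2). The summed log2 fold was 0.47 ± 0.33 for axon guidance, 0.64 ± 0.53 for striatal neuron hosts, -0.02 ± 0.56 for cortical excitatory neuron hosts and -0.12 ± 0.56 for inhibitory neuron hosts (SE, 3 against 3 libraries). It was 0.29 ± 0.52 for oligodendrocyte precursors, 0.04 ± 0.63 for microglia, -0.95 ± 1.09 for endothelial cells and pericytes and 0.11 ± 0.80 for ependyma and choroid plexus. For pathways it was 0.75 ± 0.73 for hypoxia response, 0.54 ± 0.79 for inflammatory signalling, -0.12 ± 0.46 for cell death and survival, -0.86 ± 1.11 for cell cycle and 0.10 ± 0.72 for circRNA biogenesis factors. Single hosts carried much of some lists: Dgkb held 49.3% of striatal reads and Kdm4c 92.3% of hypoxia reads. Without its most abundant host the fold was -0.08 for striatal neurons, -1.11 for ependyma and choroid plexus (without Dnah9), 0.22 for inhibitory neurons (without Grip1) and -0.38 for circRNA biogenesis factors (without Rbfox2), each with its sign turned. The sums for cortical excitatory neurons, synaptic release and brain circRNA hosts, all near 0, turned as well (to 0.06, 0.03 and -0.05). It was -0.16 for endothelial cells and pericytes (without Flt1, 65% of reads), -0.18 for cell cycle (without Atad2) and 3.27 for hypoxia, where Kdm4c leaves few reads. Without its most abundant host the sum moved to 0.03 for oligodendrocyte precursors (without Dscam), 1.18 for inflammatory signalling (without Il1rap) and 0.44 for microglia (without Plxdc2). It was 0.64 for axon guidance, 0.31 for voltage-gated ion channels, 0.04 for the glutamate receptor list, -0.39 for astrocytes and -0.49 for cholesterol and lipid synthesis. Dgkb, Kdm4c, Dnah9, Grip1, Rbfox2, Flt1, Atad2, Dscam, Il1rap and Plxdc2 were named after their values were seen. Hosts of circRNAs widely described in brain took 9.25% ± 0.13 and 9.30% ± 1.39 (SD, n = 3), and of 11 tested members 1, Erbin, passed both over all hosts and adjusted over the list alone (edgeR adjusted p = 0.00753 over the list alone). In that list Camsap1 (0.74 ± 0.51) and Rere (0.33 ± 0.27) did not pass.

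**Figure D2:**
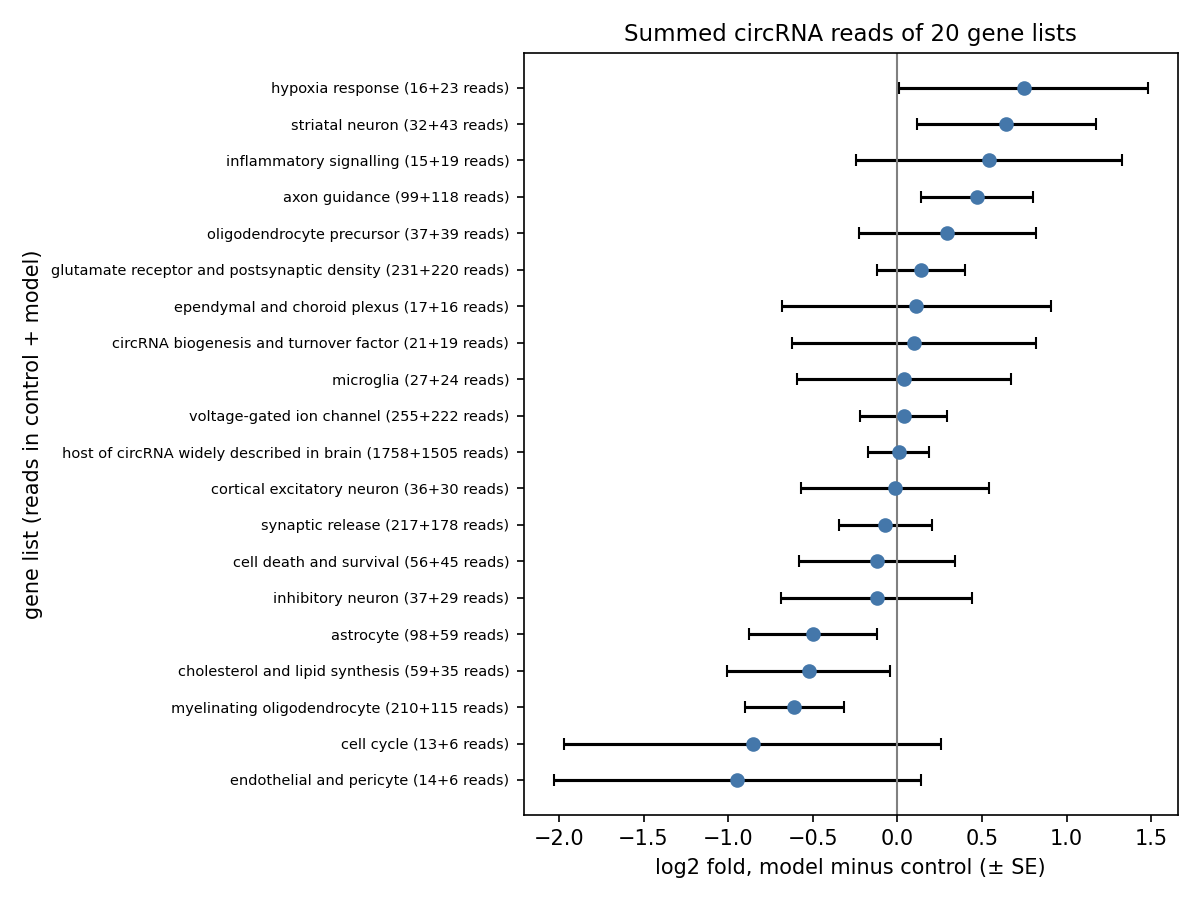
The log2 fold of summed back-splice reads (horizontal axis, model minus control; points, error bars are SE from edgeR on 3 against 3 libraries) for each of 20 gene lists, with reads in controls and model rats beside each name. The myelinating oligodendrocyte list lies at -0.61 ± 0.29 and the hypoxia response list at 0.75 ± 0.73, and none of the 20 passes after adjustment.

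Of the 20 list sums, 0 passed in edgeR after adjustment and 1, myelinating oligodendrocyte, had an unadjusted p under 0.05. Of lists with a tested member, only the brain circRNA hosts had 1 past the threshold, over all hosts or adjusted over the list alone. The other such lists had 1 or 2 tested members each. Lists such as axon guidance, cell cycle, microglia and hypoxia response had 0, so no member of theirs could pass. The planned camera test could be run on the brain circRNA hosts only. It gave adjusted p = 0.678 with the preset correlation and 0.75 with an estimated correlation, and fry gave 0.653. Many lists held few reads (13 in controls and 6 in model rats for cell cycle, 27 and 24 for microglia). The SE of their log2 folds was 1.11 and 0.63, so even 2-fold or larger changes in such lists could be missed. This was not simulated for such lists. In 10 simulations with all synaptic release hosts changed 2-fold, the list sums called that list 10 times and other lists 2 times.

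Use of alternative circRNAs within a gene was testable for 5 host genes, Eri3, Rere, Arhgap32, Sergef and Tasor (the last is outside the naming rule). None passed in limma's diffSplice. Eri3 had the smallest unadjusted p, which was above 0.05 (limma diffSplice F test per gene, adjusted p = 0.802). In edgeR its 4-exon circRNA1395 had a log2 fold of -0.53 ± 0.44 and its 3-exon circRNA1394 one of 0.33 ± 0.42 (SE).

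Whole libraries were compared by their composition. At the same depth in each library, 2048 ± 48.1 distinct circRNAs were seen in controls and 1981 ± 92.7 in model rats (SD, n = 3; exact permutation p = 0.5). The 10 most abundant circRNAs took 10.6% of reads in controls (SD 0.282), with a model minus control difference of -0.556 points (exact permutation p = 0.5, n = 3). Counting circRNAs with at least 2 reads, or the single most abundant circRNA, turned the direction of these 2 measures. With at least 2 reads, 800.3 ± 20.4 circRNAs were seen in controls and 844.2 ± 26.4 in model rats, and every model library lay above every control library (SD, n = 3; exact permutation p = 0.1). Intron-derived ciRNAs took 4.30% ± 0.502 and 5.02% ± 0.906 of reads (exact permutation p = 0.3, n = 3). The read-weighted mean log2 genomic span of exonic circRNAs was 13.17 ± 0.0151 and 13.15 ± 0.0819 (exact permutation p = 0.8, n = 3), and its direction turned without model rat 2. With 3 against 3 rats the smallest p possible is 0.1. Summed SRPBM was 148900 ± 4550 in controls and 128800 ± 10900 in model rats, with every model library below every control library (SD, n = 3; exact permutation p = 0.1).

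The authors' deposited table marks 35 circRNAs as changed, 13 higher and 22 lower in model rats, by p under 0.05 and a fold of at least 2. Its lowest q-value is 0.309, for Stk39 circRNA1632 (chromosome 3, 53101143 to 53120229, 4 exons, 38 reads in controls and 3 in model rats), so none passes at 0.05 by q. This circRNA was named after its values were seen. In the authors' deposited table its log2 fold is -3.64, that of the Erbin circRNA -1.99 and that of the Atrnl1 circRNA -1.42. Of the 35, 3 had enough reads for the edgeR test here, the circRNAs of Erbin, Atrnl1 and Slc8a1. In 13 of the 35, 1 group had no read. Of these, a circRNA of Zranb1 had 0 reads in controls and 12 in model rats, 4.67-fold higher against a floor of 3 reads over the group. The summed circRNAs of Zranb1 had 9, 24 and 30 reads in controls against 26, 19 and 15 (log2 fold 0.16 ± 0.47, SE). A circRNA of Mef2d, a transcription factor gene, had 11 reads in controls and 0 in model rats, 3.14-fold lower against the same floor (both named after their values were seen). The folds against the floor take the reads of the other group as exact, so they are not lower bounds.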

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

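Alternatives added after the data were seen were the 6-read and 10-read filters, the authors' divisors, DESeq2 without a filter, list sums and junction reads per divisor. The count of changed circRNAs (2, both lower) was 0 with DESeq2 size factors, 0 without a filter, 1 with at least 10 reads in 3 libraries, 0 at 10 reads in all and 0 in DESeq2 without a filter. It was 2, the same circRNAs, in DESeq2, limma voom, library totals, 6 reads in all and the authors' divisors. The divisors moved the median log2 fold of tested circRNAs to -0.22 and of host genes to -0.23. Leaving out 1 library gave 0 to 1 circRNAs and 0 to 4 host genes. The circRNA count was 1 without model rat 2 and 0 without any other library. The count of changed host genes (2) was 4 without model rat 1 (Stk39, Erbin, Atrnl1, and Cacna2d3 as the only higher one), 0 without any other library and 0 in DESeq2 without a filter, and 2 to 3 in the remaining settings. In limma voom the 2 were Erbin and Atrnl1, and Stk39 was lost (adjusted p = 0.122). Fewer samples and more features tested (79 to 90 circRNAs against 60) go with each left-out library. Erbin circRNA1769 ranged from -2.002 to -1.40 in log2 fold (adjusted p 0.0022 to 0.781) and Atrnl1 circRNA2141 from -1.52 to -0.89 (0.00399 to 0.969) over 17 settings. Host Stk39 ranged from -4.43 to -2.66 (adjusted p 0.00464 to 0.922) and host Erbin from -1.97 to -1.37 (0.00515 to 0.534). The gene list count (0) was 1 in camera with 6 reads in all (myelinating oligodendrocyte), a call lost with an estimated correlation and absent in fry. Without 1 library it was 0 to 1: 0 in each planned camera fit, which tested 1 list, 1 in camera with 6 reads without control 1 or without model rat 2, and 1 in the list sums without model rat 2, each time myelinating oligodendrocyte. The list sums gave 0 without any other library.

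Replicate numbers gave no sign of pairing. After each group's mean was subtracted from log2 CPM, same-numbered control and model libraries correlated at -0.0832, -0.115 and -0.001 over circRNAs. Over host genes these values were -0.0466, -0.159 and -0.0965. Differently numbered libraries gave -0.0721 to 0.134 over circRNAs and -0.0446 to 0.121 over host genes. With the replicate block 2 circRNAs and 3 host genes were called, Atrnl1 added. The planned camera test of 1 list, the list sums and the isoform test gave 0 calls with it, and camera with 6 reads in all gave 1, myelinating oligodendrocyte (adjusted p = 0.026 in camera), as without it.

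Distinct circRNAs (-67.4, model minus control) reversed to 43.9 with at least 2 reads, and the share of the top 10 (-0.556 points) to 0.269 for the top 1. Without 1 library these ranged from -101 to -14.5 and from -1.01 to -0.0655, the ciRNA share from 0.295 to 1.19 points, mean log2 span from -0.0601 to 0.0217 and summed SRPBM from -25700 to -14800. The cause was not tested for any of these. Folds near 0 of abundant circRNAs that passed no test also reversed. With DESeq2, Dtnb turned to 0.008 and Arid1a to 0.081, and with its size factors in edgeR to 0.009 and 0.079. Without a filter, Zfp532 turned to -0.067 and Setbp1 to -0.018. With 10 reads in 3 libraries Arid1a turned to 0.009, and in DESeq2 without a filter to 0.03. With 6 reads in all, Nfix turned to -0.019, Zfp532 to -0.121 and Setbp1 to -0.06, and with 10 reads in all Zfp532 to -0.033. With the authors' divisors, Nfix turned to -0.089, Unc79 to -0.073, Zfp532 to -0.201 and Setbp1 to -0.127. With 1 library left out, the log2 folds that crossed 0 ranged as follows: Arid1a circRNA1417 -0.317 to 0.316, Dtnb circRNA1168 -0.18 to 0.203, Nfix circRNA746 -0.004 to 0.446, Setbp1 circRNA863 -0.099 to 0.373, Ttc3 circRNA189 -0.502 to 0.073, Unc79 circRNA1253 -0.048 to 0.348, Zfp532 circRNA848 -0.118 to 0.196, host Grm5 -0.387 to 0.893, host Magi2 -1.178 to 0.393, host Ptprd -1.689 to 0.207, host Rims1 -1.036 to 0.027. The cause was not tested.

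Over single named circRNAs and host genes, 722 of 799 values kept their direction and side of the threshold, 33 lost a call, 8 gained one and 36 reversed. Most of these values belong to features that did not pass in the main setting and so had no call to lose. Of 17 alternative settings, the Erbin circRNA passed in 8, the Atrnl1 circRNA in 6, host Stk39 in 10 and host Erbin in 11. Of all circRNAs 52.3% rested on 1 read. In simulation, of changed circRNAs that passed the main filter (most did not), 28.6% were called at 2-fold and 84.7% at 4-fold, and of those past the 6-read filter 2.75% and 24.2%.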

Other observations

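Tests on the Atrnl1 locus, the Y-linked reads, dilution by other RNA and the comparison of junction reads per divisor were chosen after the results were seen. Junctions on the Y chromosome had 2, 9 and 2 reads in controls 1 to 3 and 0 in each of the 3 model libraries. In controls, Uty had 1, 7 and 0 reads and Kdm5d, a histone demethylase gene, 1, 0 and 2. The exact Poisson 95% interval was 4.12 to 17.1 reads in control 2 and 0.242 to 7.22 in controls 1 and 3. On the same interval a model library with 0 reads allows up to 3.69. Genes and circRNAs of the Y chromosome, and those missing from a single library, were named after their values were seen.

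A depth too low to see Y-linked reads is argued against: at the control rate 11.1 reads were due in the model libraries, and the Poisson chance of none was 1.47e-05 (0.0216 without control 2 and with each junction counted once per library). Reads of X-linked homologs placed on the Y chromosome stay open: 6 homologs had 89 reads in controls and 104 in model rats (Fisher's exact test against Y-linked reads, two-sided p = 7.13e-05), but p was 0.108 without control 2 and with each junction counted once. Control 2, with 7 Uty reads, was also the only library with 0 reads of circRNA933 of Kdm6a, the X-linked homolog of Uty (17 to 20 in the others), and whether those reads were placed on Uty was not tested. These Fisher and Poisson tests cover counting error only, not the spread between rats, and the 3 controls differed in rate (exact multinomial test by 100000 resamples, p = 0.0202). A different share of male rats in the 2 groups may account for the pattern and stays open, because the labels give no sex and the reads are few. If so, sex and model cannot be told apart in the comparisons here.

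The lower Erbin and Atrnl1 circRNAs were weighed against 3 explanations. Fewer reads from oligodendrocytes were not among them and stay open: their list sum had a log2 fold of -0.61 ± 0.29 (SE, edgeR adjusted p = 0.799). Scaling is argued against, since over 4 scalings the fold nearest to 0 was -1.14 on the log2 scale and each fold lay over 2 SE below 0, though calls were lost with DESeq2 size factors. Fewer reads from neurons as a whole are argued against, while fewer reads from a single neuron type were not tested as a cause. The summed neuronal function lists without Erbin, Atrnl1 and Slc8a1 (69 hosts) had a log2 fold of 0.13 ± 0.159 (SE). Slc8a1 was itself lower in model rats, and leaving it out moved the ion channel sum from 0.04 to 0.31. With it, the sums were 0.14 ± 0.26 for the glutamate receptor list, -0.07 ± 0.27 for synaptic release and 0.04 ± 0.26 for ion channels (SE). A change of the whole Atrnl1 locus stays open: its other 24 detected circRNAs, summed, had a log2 fold of -0.84 ± 0.397 (SE, edgeR unadjusted p = 0.0501). This just missed the bound set for a change of the locus, p under 0.05. It also missed the bound set against it, a fold more than 2 SE above the -1.22 of circRNA2141. An effect of the model itself is a hypothesis that may hold, but the 10 splits of 6 libraries are too few for a share under 0.05. The real split called 2 circRNAs against at most 0 in the other splits, and 2 host genes against at most 1, and 1 of the 10 splits, the real one, gave as many in each case.

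Fewer junction reads per divisor were seen in every model library, from 118120 to 139940 summed SRPBM against 144930 to 153860 in controls. A few abundant circRNAs are argued against as the cause, since without the 10 most abundant the log2 ratio was -0.202 (-0.21 with them) and the groups stayed apart. Dilution of all circular RNA by other RNA could lower exonic circRNAs and ciRNAs alike. Exonic circRNAs had a log2 ratio of -0.22 and ciRNAs 0.0, but the ciRNA share of single libraries overlapped between groups, so dilution is not excluded. RNase R efficiency was not tested, and the comparison cannot pass at 3 against 3 (exact permutation p = 0.1).

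A few abundant circRNAs were missing from a single library. Kdm6a circRNA933 (chromosome X, 4407815 to 4430117, 4 exons) had 17 to 20 reads in 5 libraries and 0 in control 2, where 20.4 reads were due at the rate of the others. Control 2 held 12 reads from other Kdm6a circRNAs, among them 3 from circRNA2983, which had 0 in the other libraries. Ntrk2 circRNA420 and Ambra1 circRNA1651 had 0 reads in control 3 and at least 7 in each other library, and Pde3b circRNA2037 had 0 in model rat 3 and at least 7 elsewhere.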
